A study of Arabidopsis thaliana with 33 samples.

How the data were processed

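Leaf RNA was hybridised to Affymetrix arrays as biotin-labelled targets made with a 3' IVT kit, per the labels. The deposited values are on a log2 scale, as the spacing of the hybridisation controls shows, and the median of each column is 0. Probe summary, background correction, filter and software are not given in the sources used here, so which probe sets the authors left out, and by what rule, stays unknown. The table has 12826 probe sets, of which 54 are Affymetrix controls. The values run from -8.13 to 7.44. Each array was centred on its own median, so a change shared by most genes cannot be seen, and a shift in many genes would move the others the opposite way.

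Genes were named from the annotation given with the platform, updated by gene identifier with a table of assembly TAIR10.1. Of the 12772 tested probe sets 6898 name 1 gene, 272 name several and 5602 are not listed there and stay unnamed. Where a gene had several probe sets (46 genes) the one with the highest mean over all arrays was used.

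Groups came from the sample labels. limma 3.58.1 in R 4.3.3 was fitted to all 33 arrays with a mean for each of the 8 groups and no block, so that all groups share 1 estimate of spread, and probe sets with a Benjamini-Hochberg adjusted p under 0.05 within a contrast were called. All adjusted p-values of single genes are limma's. The 13 planned contrasts were the 4 CO2 effects, 2 CO2 by N interactions, 4 N effects, midday against midnight, and 2 CO2 by time interactions. These contrasts, their alternatives and 33 gene lists were fixed from the labels before any value was seen. Lists were tested with camera at a preset correlation of 0.01, for lists with 5 or more measured members, with Benjamini-Hochberg adjustment over lists within a contrast; adjusted p with an estimated correlation is given beside each call. Because few of the listed genes are named in the annotation, 6 of the 33 lists could be tested. Lists with no measured member were cell division, circadian clock, flowering time, heat shock, mitochondrial import, phosphate starvation, salicylic acid defence, sulfate limitation, and markers of floral organs, phloem, root and xylem. A cytosolic ribosomal list, planned from gene descriptions, could not be formed that way. Over the 13 planned contrasts, interactions included, 16 of 78 tests of the planned lists passed, 1 with an estimated correlation and 9 with fry; over the 9 averages 22 of 54 passed, 0 with an estimated correlation and 11 with fry. Fry asks whether a list moves on balance one way. Without a test, 2 list members were left out because the annotation gives their code another identity.

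Genes were named by a rule fixed in advance: among single-gene probe sets past the threshold, the 8 largest rises and falls for CO2 effects and N effects at ambient CO2, 5 for the other contrasts, and the 4 members with the smallest p of the respiration, nitrogen and photosynthesis lists. Not all of those members are given in the text: the list members it names, and the genes whose group means it prints, were picked after their values were seen. The 9 averaged contrasts were added only after the planned contrasts had given almost no calls; the rule for the averages (the 8 largest each way for the mean CO2 and mean N effects) was set after their counts and before their genes were read. A further 9 lists were written after the annotation, counts and principal components had been seen, and before the value of any member; those of plastid-encoded genes, protein folding, tubulins and glutathione transferases hold the symbols found in the annotation, and the ribosomal list was made by locus code. The size of a CO2 effect is the root of the mean over probe sets of the squared log2 effect minus its squared standard error, with a jackknife error over arrays. Array quality was judged from the log2 ratio of 3' to 5' control probe sets over 6 pairs.

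The fit was checked on simulated data with the real means and spreads, and the list tests were run on them too. This simulation drew each probe set independently, with the same spread in all arrays. It holds no correlation between genes, so it cannot check the preset correlation of the list tests. In it, limma recovered 64 of 100 genes changed by 1 on the log2 scale and 10 of 100 changed by 0.5 for the CO2 effect at ample N and midday, 84 and 21 at ample N and midnight, 78 and 13 at limiting N and midday, 73 and 18 at limiting N and midnight, and 97 and 82 for the average over all conditions, each on 12772 probe sets. A second simulation, added later, put a CO2 effect under limiting N alone; the CO2 by N interaction recovered 46, 53 and 78 of 100 genes at a log2 difference of 1 at midday, at midnight and averaged over time, 6, 8 and 16 at 0.5, and 96, 95 and 99 at 2. Alternatives were another normalization, a filter on the 30% dimmest probe sets, fits to fewer arrays, a replicate block, eBayes with trend and robust, array weights, a 1.5-fold minimum, each replicate left out in turn and, chosen after seeing the data, 2 doubted arrays left out together (ambient ample midnight replicate 4, for its high 3' to 5' ratio, and elevated limiting midnight replicate 1, for its second principal component and low array weight) and the 3' to 5' ratio as a covariate. The 2 doubted arrays held the extreme scores of the second principal component, 56.6 and -57.1 in the order given. At midnight ambient arrays scored 2.1 or higher on it and elevated arrays 7.8 or lower. Leaving both out therefore also removes the ends of an axis that goes with CO2. The second of them had no high 3' to 5' ratio (1.72). A pseudocount, planned for linear values, was not needed. No coordinates are given, since the build behind the array annotation is not stated.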

Results

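Leaf RNA of Arabidopsis thaliana (Col) was measured on Affymetrix arrays in 33 samples from plants grown at 370 ppm (ambient) or 750 ppm (elevated) CO2, with ample (6 mM NH4NO3) or limiting (0.25 mM NH4NO3) nitrogen. The youngest fully expanded leaves were taken on day 35 at midday or midnight, which gives 8 groups of 3 to 5 arrays. There were 15 midday and 18 midnight arrays. The number of arrays limits the precision of every value below. Values are log2 expression with the median of each array set to 0, so a value states a level relative to that array's own median. The labels do not say whether replicates are separate plants, pools or chambers, so p-values measure the spread between these samples only.

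At ample nitrogen, no single probe set passed the threshold for a difference between elevated and ambient CO2 at either time. At midday the member of the tricarboxylic acid (TCA) cycle list with the smallest p was AT4G26910, the 2-oxoglutarate dehydrogenase E2 subunit, with a log2 difference of 0.745 (SE 0.22, adjusted p = 0.316). PRK, the phosphoribulokinase of the Calvin-Benson cycle, had a log2 difference of -0.36 (SE 0.17, adjusted p = 0.652), and AT5G63680, a pyruvate kinase, one of 0.49 (SE 0.2, adjusted p = 0.525). At midnight NDB2, an external mitochondrial NADH dehydrogenase, had a log2 difference of 1.297 (SE 0.28, adjusted p = 0.0601) and SDH2-1, a succinate dehydrogenase subunit, one of 0.54 (SE 0.14, adjusted p = 0.0921). CYTC-2, a cytochrome c, had one of 0.67 (SE 0.19, adjusted p = 0.0998), and SBPASE of the Calvin-Benson cycle one of -0.65 (SE 0.2, adjusted p = 0.111). Of the 16 measured TCA cycle genes, 13 lay above 0 at midday, and the list passed the camera test (adjusted p = 0.0337). That call was lost with an estimated correlation (adjusted p = 0.534). All 7 measured chlorophyll genes lay below 0 at midday (median -0.07, adjusted p = 0.292) and at midnight (median -0.20, adjusted p = 0.252). So did 7 of 8 light-reaction genes at midday (adjusted p = 0.0772) and 6 of 8 at midnight (adjusted p = 0.514). None of these list tests passed. limma's test called 0 probe sets at midday and 0 at midnight, with 961 and 2398 at an unadjusted p under 0.05. Chance alone gives a mean of 639 of the 12772 tested. Genes that vary together can move such counts far to either side of that mean, so these counts are not read as evidence for or against an effect. With array weights limma called 121 at midday and 0 at midnight, and with only the arrays of the groups compared 70 and 0. The midnight count was 415 without ambient ample midnight replicate 2, 35 without elevated ample midnight replicate 4, 15 without ambient ample midnight replicate 1, 15 without the dimmest probe sets, and 0 without each of the other 7 arrays.

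Under limiting nitrogen, genes of chlorophyll synthesis and the light reactions again lay on the low side at elevated CO2. All 7 measured chlorophyll genes lay below 0 at midday (median log2 -0.415) and at midnight (median -0.49), with 4 passing at each time when adjusted over the list alone and 0 over all probe sets. The camera test gave adjusted p = 0.000138 at midday and 0.00114 at midnight, and with an estimated correlation adjusted p = 0.24 and 0.224. The 8 light-reaction genes also lay below 0 at midnight (median -0.34, adjusted p = 0.00161, and adjusted p = 0.224 with an estimated correlation). Of the 16 TCA cycle genes 12 lay above 0 at midnight (adjusted p = 0.0235, and adjusted p = 0.24 with an estimated correlation).

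Single probe sets rarely passed here either. AT3G15350 rose at midnight from -0.01 ± 0.27 (SD, n = 4) to 0.89 ± 0.33 (SD, n = 4), 1.87-fold (limma adjusted p = 0.0453). HON4, which encodes a linker-histone-like protein, fell from 2.12 ± 0.14 (SD, n = 4) to 1.51 ± 0.09 (SD, n = 4), with limma adjusted p = 0.0453. The other 2 of the 4 midnight calls are probe sets that the annotation used does not name, with log2 changes of -1.45 and 2.07. NDB2 had a log2 difference of 1.47 (SE 0.31, adjusted p = 0.0589), enlarged by the doubted elevated replicate 1 at 2.258, with the others of its group at 0.162 to 1.093. AT5G56350, a pyruvate kinase, had a log2 difference of 0.59 (SE 0.14, adjusted p = 0.0934). PORB, a protochlorophyllide reductase, had one of -0.77 (SE 0.22, adjusted p = 0.106), HPR, the photorespiratory hydroxypyruvate reductase, one of -0.60 (SE 0.18, adjusted p = 0.124), PRK one of -0.49 (SE 0.16, adjusted p = 0.13), and ATPC1, the chloroplast ATP synthase gamma subunit, one of -0.38 (SE 0.14, adjusted p = 0.162). At midday HEME2 of chlorophyll synthesis had a log2 difference of -0.64 (SE 0.17, adjusted p = 0.181) and AT1G80380, a glycerate kinase of photorespiration, one of -0.45 (SE 0.18, adjusted p = 0.314). limma called 0 probe sets at midday (1491 at an unadjusted p under 0.05, 203 with array weights) and 4 at midnight (2246, and 37). The midnight count moved with every single array left out: it was 384 without elevated replicate 3, 52 without elevated replicate 2, 1 without ambient replicate 2, and 0 without elevated replicate 1 or 4 or ambient replicate 1, 3 or 4. The midday count was 15 without elevated replicate 4, 3 without elevated replicate 2, 2 without ambient replicate 2, and 0 without each of the others.

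**Figure D1:**
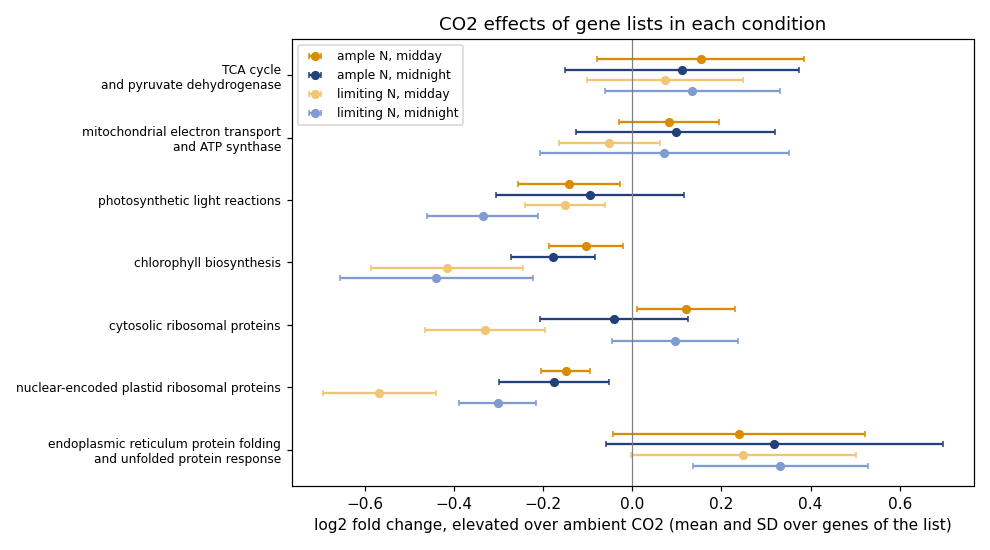
Mean log2 fold change, elevated over ambient CO2, of each gene list in the 4 conditions, with bars of 1 SD over the genes of the list. Chlorophyll genes lie at a mean of -0.42 and -0.44 under limiting N at midday and midnight.

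The series asks whether limiting nitrogen changes the CO2 response, and the test of that difference called no gene. For the CO2 by N interaction limma called 0 probe sets at midday and 0 at midnight, and 0 with array weights. At an unadjusted p under 0.05 there were 298 and 347. The mean by chance is 639, but genes that vary together can move such counts, so the low counts do not show that there is no interaction. In simulated data in which CO2 acted under limiting nitrogen alone, this test recovered 46 of 100 genes at midday and 53 at midnight at a log2 difference of 1, and 6 and 8 at 0.5. Small differences would mostly be missed. The simulated probe sets were drawn independently with equal spread in all arrays, so recovery in the real data may differ. All 7 chlorophyll genes had a lower CO2 effect under limiting than ample nitrogen at midday (median difference -0.25, adjusted p = 0.00929) and midnight (median -0.17, adjusted p = 0.0115), as did 29 of the 35 measured electron transport genes at midday, with 6 the other way (median -0.14, adjusted p = 0.0155), and 7 of 8 light-reaction genes at midnight (adjusted p = 0.00756). With an estimated correlation these tests gave adjusted p = 0.667, 0.454, 0.667 and 0.454. HEME2 had the smallest p among chlorophyll genes at midday (difference -0.61, SE 0.255, adjusted p = 1), and LHCB4.2, a light-harvesting protein, among light-reaction genes at midnight (-0.89, SE 0.33, adjusted p = 1).

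No difference in the size of the CO2 effects between the nitrogen supplies was resolved. The root mean square log2 effect, after taking off the sampling error, was 0.19 (jackknife SE 0.109) at ample and 0.18 (SE 0.119) at limiting nitrogen at midday, and 0.27 (SE 0.108) and 0.29 (SE 0.177) at midnight. Single arrays moved these sizes: the first ran from 0.10 without elevated ample midday replicate 3 to 0.236 without its replicate 1, and the last from 0.142 without elevated limiting midnight replicate 1 to 0.379 without its replicate 3. The limiting minus ample difference was -0.01 (SE 0.159) and 0.02 (SE 0.213), errors that leave room for a smaller or a larger response under limiting nitrogen. Across probe sets, which are not independent replicates, the effects at the 2 supplies correlated with r = 0.574 (jackknife SE 0.315) at midday and 0.696 (SE 0.147) at midnight. The 2 effects had the same sign for 66.3% and 72.1% of probe sets. They share no arrays, but many genes can vary together between arrays of a group. With 3 to 5 arrays per group, these correlations alone do not show a shared response to CO2. Without elevated ample midday replicate 3 the midday correlation was 0.342.

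Limiting nitrogen at ambient CO2 raised AT1G68600, a malate-transporter family gene, at midnight from -0.33 ± 0.65 (SD, n = 5) to 2.19 ± 0.32 (SD, n = 4), 5.76-fold (limma adjusted p = 0.000303). It also raised AT5G45650, a subtilase (2.52-fold, adjusted p = 0.00224), AT5G64550 (2.57-fold), CDI (2.41-fold), AT2G39920 (2.02-fold), AT4G34950 (1.77-fold) and AT5G48370 (1.71-fold). Lower at midnight were SAPX, a stromal ascorbate peroxidase (from 1.61 ± 0.64, SD, n = 5, to 0.29 ± 0.43, SD, n = 4, limma adjusted p = 0.00838), AT5G26200 (2.57-fold lower), AT4G33960 (2.42-fold), AT3G43670 (2.39-fold), AT4G37180 (2.32-fold), AT5G59400 (1.96-fold) and AT1G15710 (1.7-fold). At midday 1 probe set passed, AT2G16660, which rose from -0.72 ± 0.57 (SD, n = 4) to 1.84 ± 0.05 (SD, n = 4), 5.89-fold (limma adjusted p = 6.91e-05). AT1G68670, a nitrate-responsive repressor, had a log2 difference of -0.745 at midnight (SE 0.2, adjusted p = 0.126). In all, limma called 19 higher and 25 lower at midnight and 1 at midday (1258 and 460 at an unadjusted p under 0.05). Array weights gave a far higher midday count, listed below with the other settings. The midnight count was 15, 17 and 21 without ambient limiting midnight replicate 4, 3 and 1, and 29 without ambient ample midnight replicate 5. With only the 9 arrays of those groups it was 3. The midday count was 2 without ambient limiting midday replicate 2 or 4.

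At elevated CO2 limiting nitrogen raised AT1G68600 again, 4.91-fold at midday (limma adjusted p = 0.00966) and 3.05-fold at midnight (adjusted p = 0.0411). AT1G62480 fell at midday from 1.59 ± 0.64 (SD, n = 3) to -0.64 ± 0.36 (SD, n = 4), 4.72-fold (limma adjusted p = 0.0057), and AT1G03820 fell 2.2-fold. At midnight AT5G26200 fell 3-fold, COR15B, a cold-responsive chloroplast protein, 2.93-fold, AT3G15450 2.5-fold, AT5G14120 2.47-fold and SAPX 2.32-fold, while AT2G29670 rose 1.84-fold. PSAN, a photosystem I subunit, fell by 0.77 on the log2 scale (SE 0.13, adjusted p = 0.00425), and 7 of the 8 light-reaction genes lay below 0 (median -0.44). That list gave adjusted p = 1.69e-08, and adjusted p = 0.0225 with an estimated correlation. Of the 35 electron transport genes 31 lay below 0 at midday (adjusted p = 0.00393, and adjusted p = 0.438 with an estimated correlation). AT1G25550, of the same repressor family as AT1G68670, had a log2 difference of -0.66 at midday (SE 0.24, adjusted p = 0.561). limma called 1 higher and 6 lower at midday and 4 higher and 17 lower at midnight, and 0 and 0 with only the arrays of the groups compared. Array weights moved both counts the other way, to higher ones listed below with the other settings. The midday count was 52 without elevated ample midday replicate 3, 0 without its replicate 1 or 2, and 1 without elevated limiting midday replicate 1. At midnight it was 5, 6, 7 and 12 without elevated ample midnight replicate 5, 2, 1 and 4, and 1, 11 and 12 without elevated limiting midnight replicate 4, 1 and 3.

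Most tested probe sets differed between midday and midnight arrays, though a processing batch that goes with time was not excluded, least of all for the smaller changes. Higher at midday were AT5G35970 (23.9-fold), AT2G23840 (16.9-fold), CYP71B26, a cytochrome P450 (16.8-fold), AT5G57345 (12.8-fold) and AT3G01060 (12.2-fold). Lower at midday were AT3G59350 (13.2-fold), AT5G62900 (8.62-fold), AT5G51570 (8.01-fold), AT1G22890 (7.8-fold) and AT1G26665 (7.6-fold). Of the 8 light-reaction genes 7 were higher at midday, among them LHCB4.2 by 2.76 (SE 0.12) and PSBY by 1.298 (SE 0.08) on the log2 scale, and 11 of 16 TCA cycle genes were lower, among them IDH-V, an isocitrate dehydrogenase, by a log2 change of -0.999 (SE 0.05), and AT5G65750, a 2-oxoglutarate dehydrogenase E1 subunit, by -0.94 (SE 0.105). These lists gave adjusted p = 4.84e-05 and 0.00122, and adjusted p = 0.0986 for both with an estimated correlation. TMT1, a vacuolar sugar transporter (-2.05), SWEET11, a sucrose exporter (-1.65), PWD, a starch-phosphorylating enzyme (-2.22), and AT1G25550 (-1.99) were lower at midday, and BCAT4, of glucosinolate synthesis, was higher (2.66). limma called 4272 probe sets higher and 3971 lower, of 12772. Of the 37 spike-in control probe sets, which are added in the laboratory, 18 differed between midday and midnight arrays (permutation test, adjusted p under 0.05), 14 of them higher at midday, and the labels name no processing batch.

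The CO2 by time interactions called 0 probe sets at ample and 0 at limiting nitrogen, with limma (420 and 616 at an unadjusted p under 0.05) and with array weights. NDB2 had the smallest p of the alternative respiratory genes under limiting nitrogen, with a midday minus midnight difference in its CO2 effect of -1.15 (SE 0.44, adjusted p = 0.97).

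Because so few probe sets passed in single conditions, 9 averages of these contrasts were added after those counts had been seen, and all 9 are given. Averaged over nitrogen and time, CHI, a chitinase, was 7.25-fold higher at elevated CO2 (SE 0.4 on the log2 scale, adjusted p = 0.000251), PDF1.2 and PDF1.2b, both plant defensins, 3.26-fold (adjusted p = 0.00206) and 3.01-fold (adjusted p = 0.0053, on a probe set of a type that may also bind related transcripts, so not a separate measure), with SAL2 (3.42-fold), AT4G00700 (3.52-fold), AT5G18470 (3.28-fold), AT3G48650 (3.1-fold) and AT2G18690 (3.01-fold). Of these, AT3G48650 and AT4G00700 lay well below the array median with a wide spread in ambient leaves. At ample nitrogen and midnight they were at -3.55 ± 2.32 and -2.77 ± 1.66 (SD, n = 5). WRKY53, a regulator of leaf senescence, rose by 1.16 (SE 0.22, adjusted p = 0.00106) and AMY1, an alpha-amylase, by 1.103 (SE 0.23, adjusted p = 0.00193) on the log2 scale. STOMAGEN, a peptide that promotes stomatal formation, was 2.2-fold lower (adjusted p = 0.000755), with AT1G60590 (3.02-fold), AT3G13000 (1.89-fold), AT2G10940 (1.86-fold), AT5G01015 (1.81-fold), AT3G05730 and AT1G69523 (both 1.8-fold) and AT3G16670 (1.75-fold). The mean of PDF1.2 was higher in elevated leaves in every condition, but its arrays overlapped. At ample nitrogen and midnight it was at -0.23 ± 0.87 (SD, n = 5) in ambient and 1.09 ± 2.01 (SD, n = 5) in elevated leaves. At limiting nitrogen and midday ambient replicate 2 (2.888) lay above every elevated array (highest 2.853). CHI was at -2.19 ± 0.68 (SD, n = 4) in ambient and 1.39 ± 1.38 (SD, n = 3) in elevated leaves at ample nitrogen and midday. At midnight it was at -0.87 ± 0.84 (SD, n = 5) and 1.94 ± 0.64 (SD, n = 5). At limiting nitrogen it was at -1.38 ± 1.73 (SD, n = 4) and 0.56 ± 2.19 (SD, n = 4) at midday, where elevated replicates 1 (-1.17) and 4 (-1.435) lay below ambient replicate 2 (1.181), and at -0.30 ± 0.43 (SD, n = 4) and 2.80 ± 1.35 (SD, n = 4) at midnight. STOMAGEN was at 0.64 ± 0.12 (SD, n = 4) and -0.30 ± 1.08 (SD, n = 3) at ample nitrogen and midday, 1.79 ± 0.93 (SD, n = 5) and 0.44 ± 0.40 (SD, n = 5) at midnight. Under limiting nitrogen it was at 0.38 ± 0.31 (SD, n = 4) and -0.69 ± 0.38 (SD, n = 4) at midday, and 1.12 ± 0.26 (SD, n = 4) and -0.05 ± 0.90 (SD, n = 4) at midnight. Both doubted arrays were extremes for STOMAGEN and enlarged its CO2 difference. Ambient ample midnight replicate 4 stood at 3.371, with the others of its group at 1.032 to 1.759. Elevated limiting midnight replicate 1 stood at -1.325, with the others of its group at -0.019 to 0.583.

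**Figure D2:**
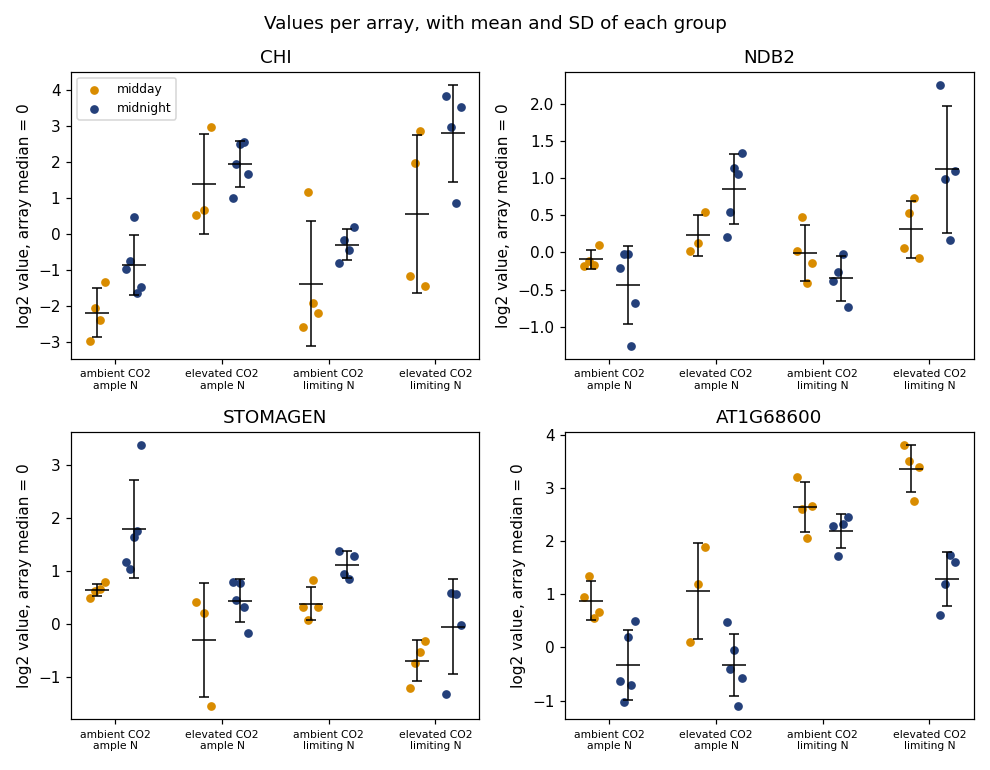
Log2 values, with each array's median at 0, of CHI, NDB2, STOMAGEN and AT1G68600 in every array, by CO2, nitrogen and time, with the group mean and SD as bars. At midnight and limiting N, NDB2 stands at a mean of -0.35 in ambient and 1.12 in elevated leaves. There the doubted elevated replicate 1 stands at 2.258 and the others of its group at 0.162 to 1.093.

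In the same average, a minority of the measured respiratory genes passed as higher, where 1080 of all 12772 tested probe sets did. The counts below are to be set beside that share. NDB2 rose by 0.86 (SE 0.16, adjusted p = 0.000805) and NDB1 fell by 0.28 (SE 0.09, adjusted p = 0.0275). Of 16 TCA cycle genes 3 rose, AT4G26910 by 0.48 (SE 0.1), SDH2-1 by 0.31 (SE 0.08) and AT5G08300, a succinyl-CoA ligase subunit, by 0.21 (SE 0.07), 0 fell and 13 did not pass. Adjusted over the list alone, 5 rose and 1 fell (adjusted p of the list = 0.01, and adjusted p = 0.264 with an estimated correlation). Among 11 glycolysis genes the pyruvate kinases AT5G63680 (0.49, SE 0.09) and AT5G56350 (0.36, SE 0.07) rose and 9 did not pass (list adjusted p = 0.653). Of 35 electron transport genes 1 rose, AT5G25450 of complex III (0.715, SE 0.258, adjusted p = 0.0461), and the list did not pass (adjusted p = 0.118).

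Calvin-Benson and photorespiration genes were mostly lower in this average. Of 4 measured Calvin-Benson genes 3 fell, SBPASE by 0.44 (SE 0.11), PRK by 0.36 (SE 0.08) and AT1G56190, a phosphoglycerate kinase, by 0.345 (SE 0.08), while RCA, the Rubisco activase, had a log2 difference of -0.19 (adjusted p = 0.0749). All 4 photorespiration genes fell, LrgB by 0.455, AT1G11860, the T protein of glycine decarboxylase, by 0.45, AT1G80380 by 0.38 and HPR by 0.365. Neither list reached the 5 members needed for a test. Of 7 chlorophyll genes 5 fell, among them CHLI2 by 0.40 (SE 0.1) and CHLM by 0.375 (SE 0.1) (list adjusted p = 0.00312, and adjusted p = 0.264 with an estimated correlation). Of 8 light-reaction genes ATPC1 fell by 0.24 (SE 0.07) and PSBY by 0.23 (SE 0.08), and 6 did not pass (list adjusted p = 0.0162, and adjusted p = 0.334 with an estimated correlation). Of the markers of other cell types 2 were measured: TRY, of trichome patterning, fell by 0.54 (SE 0.13, adjusted p = 0.0043) and FMA, of guard cells, had a log2 difference of -0.13 (SE 0.11, adjusted p = 0.421).

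limma called 1080 probe sets higher and 1645 lower for the CO2 effect averaged over all conditions, of which 439 changed at least 1.5-fold. The averages by time called 136 higher and 35 lower at midday and 656 higher and 1053 lower at midnight. Those by nitrogen called 177 higher and 104 lower at ample and 173 higher and 292 lower at limiting supply, and the averaged CO2 by N interaction called 0 (275 at an unadjusted p under 0.05, 0 with array weights). Over single arrays left out, the midday average ran from 0 (elevated ample midday replicate 3) to 327 (elevated limiting midday replicate 4), and the midnight average from 291 (elevated limiting midnight replicate 1) to 2344 (elevated limiting midnight replicate 3). The ample-nitrogen average ran from 1 (elevated ample midday replicate 3) to 639 (ambient ample midnight replicate 2), and the limiting-nitrogen average from 0 (elevated limiting midnight replicate 1 or 4, or ambient limiting midday replicate 3) to 1141 (elevated limiting midnight replicate 3).

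Averaged over CO2 and time, limiting nitrogen raised AT1G68600 (4.13-fold, adjusted p = 1.66e-08), AT2G16660 (2.47-fold), AT1G64360 (2.36-fold), AT3G16670 (2.32-fold), AT2G39920 (2.01-fold), AT1G25530 (1.92-fold), GAMMA-VPE, a vacuolar processing protease (1.88-fold), and AT5G64550 (1.86-fold). It lowered AT1G62480 (2.44-fold, adjusted p = 8.51e-06), AT3G62930, a glutaredoxin (2.27-fold), AT5G19120 (1.99-fold), AT5G26200 (1.98-fold), AT2G20670 (1.86-fold), AT2G41190 (1.77-fold), AT1G12080 (1.73-fold) and AT4G33960 (1.69-fold). The nitrate-responsive repressor AT1G25550 fell by 0.51 (SE 0.11, adjusted p = 0.0124), APL3, a subunit of the starch enzyme ADP-glucose pyrophosphorylase, rose by 0.51 (SE 0.13, adjusted p = 0.0289) and PSAN fell by 0.33 (SE 0.07, adjusted p = 0.00591). limma called 74 higher and 106 lower over all conditions, 11 and 18 at midday, and 67 and 109 at midnight. Without elevated ample midday replicate 1, 2 and 3 in turn the count over all conditions was 104, 118 and 325. The midday count was 18 without elevated ample midday replicate 1 or 2, 19 without ambient ample midday replicate 4 or elevated limiting midday replicate 1, and 47 without elevated ample midday replicate 3.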

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

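The tests on ambient ample midnight replicate 4, on the 2 doubted arrays and on the spike-in controls (their number and their size) were chosen only after the results they bear on had been seen, as was the exchange of labels for comparisons with 0 calls, where every exchange gives at least as many. The covariate of RNA quality was added after the data were seen, with its prediction written before its count. A first test of a wrong label, by correlation with each midnight group, had its margin set after its values were seen and separated the ambient groups too little; the scores given below were added after it.

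In ambient ample midnight leaves, replicate 4 lay far from its group in mean log2 3' to 5' control ratio, at 4.41 against 2.35 for the nearest array. In the same measure ambient limiting midday replicate 1 (1.89) and elevated limiting midnight replicate 1 (1.72, the lowest of its group) stood apart by small distances, and ambient ample midday replicate 1 did so in its second principal component score (11.99). Among single genes, HON4 in elevated limiting midnight replicate 1 (1.38), AT2G16660 in elevated ample midnight replicate 5 (1.97), and PDF1.2 in ambient limiting midnight replicate 4 (-1.53) and elevated limiting midnight replicate 2 (2.21) stood apart from their groups. Chance marks about 1 in 20 groups, and here 8 were marked in 21 tests of array quality and 70 of genes.

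The high ratio of ambient ample midnight replicate 4 (4.41) is consistent with truncated labelled RNA, and the ratios of all other arrays went no higher than 2.35. Its values argue against an exchanged nitrogen, CO2 or time label, and a sample from outside the series was not tested. On probe sets that a factor moved in a fit without the array scored, kept where the 2 groups differed in the same direction by over 0.5 of that effect, with 0 at the other arrays of its group and 1 at the other group, it stood at -0.051 for limiting nitrogen (ambient limiting midnight arrays 0.81 to 1.051), -0.491 for elevated CO2 (elevated ample midnight arrays 0.44 to 1.341, though other arrays of its own group reached 0.656) and 0.161 for midday (ambient ample midday arrays 0.918 to 1.021). Its correlation with the 4 midnight groups was 0.055 with its own, 0.043 with ambient limiting, -0.412 with elevated ample and -0.489 with elevated limiting. Without this array and elevated limiting midnight replicate 1 the averaged CO2 effect called 2356 probe sets.

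The averaged CO2 effect called 2725 probe sets and its interaction with nitrogen 0. The 3' to 5' ratio is an unlikely source of all these calls, since with it in the fit 2771 were called. Groups of 3 to 5 arrays are too few to show that the ratio was equal between CO2 levels: elevated minus ambient it was 0.06, -0.41, -0.1 and -0.2 (exact p = 0.83, 0.635, 0.457 and 0.2). Of 100 exchanges of the CO2 labels within groups, the true one included, 1 gave as many calls, and the highest other count was 3. Growth chambers are not named in the labels, so a chamber that goes with CO2 could give the same calls, and that was not tested.

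Most probe sets differed between midday and midnight, and so did 18 of 37 spike-in controls, by a median absolute difference of 0.55 and at most 0.75 on the log2 scale; the largest difference among all 37, of a control that did not pass, was 0.99. A processing shift no larger than that of the controls would not account for the whole pattern. Of 8243 called probe sets, 921 changed by over 0.99 by more than 2 SE, 537 higher and 384 lower at midday. The controls are several probe sets each of a few spiked transcripts, so they are not independent. The controls set no firm bound on a shift of other probe sets, so a larger batch shift that goes with time is not excluded. The 4 controls that were lower at midday were all 3' probe sets. For the smaller changes, the time of day and a processing batch, which the labels do not name, cannot be told apart, since the 18 controls differed along with time. The mean log2 3' to 5' ratio also went with time. Its group means ran from 1.73 to 1.85 at midday and from 1.92 to 2.54 at midnight, the last with the array at 4.41. Of 100 exchanges of the time labels 1, the true one, gave as many calls, with 3732 for the highest other.

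For the other comparisons the same exchange gave, as the number of groupings with at least as many calls, 35 of 35 for CO2 at ample nitrogen at midday and 35 of 35 at limiting nitrogen at midday, 100 of 100 at ample nitrogen at midnight, and 1 of 35 at limiting nitrogen at midnight. At ample nitrogen at midnight, where the true labels gave 0 calls, the highest other count was 221. For nitrogen at ambient CO2 the exchange gave 1 of 35 at midday and 2 of 100 at midnight, and at elevated CO2 1 of 35 and 2 of 100. The highest other midnight count was 44 at ambient CO2, where the true labels also gave 44. At elevated CO2 it was 38, above the 21 of the true labels. All 3 CO2 by N and both CO2 by time interactions gave 100 of 100, since no probe set was called. Exchanged labels gave up to 28 calls for the averaged CO2 by N interaction. The averages by time and by supply for CO2 and all 3 averages for nitrogen gave 1 of 100, with 581 as the highest other count for CO2 at midnight.

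Some gene lists differed in their CO2 effect between nitrogen supplies or times by the interaction test; none of these 17 calls held with an estimated correlation or with fry. Chlorophyll genes differed between supplies at midday (adjusted p = 0.00929), midnight (adjusted p = 0.0115) and on average (adjusted p = 6.63e-05). Electron transport genes differed at midday (adjusted p = 0.0155) and on average (adjusted p = 0.0169), and light-reaction genes at midnight (adjusted p = 0.00756). Cytosolic ribosomal genes differed between supplies at midday (adjusted p = 7.16e-42), midnight (adjusted p = 0.000165) and on average (adjusted p = 4.91e-12), and between times at ample (adjusted p = 0.000871) and limiting nitrogen (adjusted p = 1.28e-33). Plastid ribosomal genes differed between supplies at midday (adjusted p = 1.42e-05) and on average (adjusted p = 2.16e-05), and between times at limiting nitrogen (adjusted p = 0.0153). The plastid expression genes differed between supplies at midday (adjusted p = 0.00799) and between times at ample nitrogen (adjusted p = 0.00566), and glutathione and glycosyl transferases between supplies at midnight (adjusted p = 0.0392).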

How the results depend on the processing

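Leaving out both doubted arrays together and the 3' to 5' ratio as a covariate were chosen after seeing the data. The doubted arrays are the extremes of an axis that goes with CO2 at midnight, so leaving them out is not a removal of low-quality arrays alone. Counts that moved by over 1.5 times are given here by setting, and the cause was not tested beyond the fewer arrays or probe sets that some settings use. The mean CO2 count stayed within 1.5 times under all others but the 1.5-fold minimum, the interactions stayed at 0 under all, and the effect sizes moved by less than their jackknife errors. That error comes from the same fits with single arrays left out, so for those fits the outcome was all but fixed and shows no stability. With single arrays left out the sizes moved by over 1.5 times (0.1 to 0.236 at ample N midday and 0.142 to 0.379 at limiting N midnight). Signal over background cannot be judged from centred values. A pseudocount was not run, since the values are log2.

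With quantile normalization of all arrays, calls were CO2 limiting N midday 8. Without the 30% dimmest probe sets, calls were CO2 ample N midnight 15, N ambient CO2 midday 5. With arrays of 1 time only, calls were N ambient CO2 midday 2, N elevated CO2 midday 4, CO2 midday mean 331, CO2 limiting N midnight 0, N ambient CO2 midnight 23, N elevated CO2 midnight 5, CO2 midnight mean 412, N midnight mean 117. Under eBayes with trend and robust, calls were CO2 limiting N midnight 0, N ambient CO2 midday 3. Under array weights, calls were CO2 ample N midday 121, CO2 limiting N midday 203, CO2 limiting N midnight 37, N ambient CO2 midday 109, N elevated CO2 midday 277, N elevated CO2 midnight 46, CO2 midday mean 793, CO2 midnight mean 794, CO2 ample N mean 517, CO2 limiting N mean 1113, N mean 805, N midday mean 483, N midnight mean 308. Without both doubted arrays, calls were CO2 limiting N midnight 0, N ambient CO2 midday 4, N elevated CO2 midday 17, CO2 midday mean 566, CO2 midnight mean 219, CO2 ample N mean 513, CO2 limiting N mean 10. With the 3' to 5' ratio as a covariate, calls were CO2 limiting N midnight 11, N ambient CO2 midday 6, CO2 midday mean 288, CO2 limiting N mean 805. With only the groups compared, calls were CO2 ample N midday 70, CO2 limiting N midnight 0, N ambient CO2 midnight 3, N elevated CO2 midday 0, N elevated CO2 midnight 0, CO2 midday mean 331, CO2 midnight mean 412, CO2 limiting N mean 229, N midnight mean 117. At 1.5-fold or more, calls were midday against midnight 3566, CO2 mean 439, CO2 midnight mean 616, CO2 limiting N mean 235, N mean 60, N midnight mean 109. With an estimated correlation, calls were planned lists in planned contrasts 1, planned lists in averages 0, added lists in planned contrasts 1, added lists in averages 0. With fry, calls were planned lists in planned contrasts 9, planned lists in averages 11, added lists in planned contrasts 13, added lists in averages 10.

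With the replicate number within each time as a block, calls were CO2 ample N midnight 10, CO2 limiting N midday 2, N ambient CO2 midnight 27, N elevated CO2 midnight 13, CO2 midday mean 105. For midday against midnight that fit gave 3545. Its blocks lie within a time, so that count compares a reference block of each time and not the means of the times. It cannot be set beside the main count. Same-numbered arrays showed no clear pairing: 17 of 46 same-numbered pairs correlated over 0.1 and 10 of 33 arrays correlated best with their own number. The median correlation of same-numbered pairs was 0.036 (highest 0.446), against -0.003 for pairs with other numbers. These values do not exclude that some same-numbered arrays shared growth or processing. A call lost under the block is not read as a weaker effect.

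With each replicate left out in turn, counts ranged as follows: CO2 limiting N midnight 0 to 384, N ambient CO2 midnight 15 to 59, CO2 midnight mean 291 to 2344, CO2 limiting N mean 0 to 1141, N mean 104 to 325, N elevated CO2 midnight 1 to 20, CO2 ample N midnight 0 to 415, CO2 ample N mean 1 to 639, N ambient CO2 midday 1 to 2, CO2 midday mean 0 to 327, N midday mean 18 to 47, CO2 limiting N midday 0 to 15, N elevated CO2 midday 0 to 52.

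RCA, which did not pass for mean CO2, had a log2 difference of 0.002 (adjusted p = 0.985) under quantile normalization. The plastid-encoded photosynthesis genes lay lower in the CO2 effect, ample N, midnight (adjusted p = 0.0412, and adjusted p = 0.772 with an estimated correlation), and turned upward without both doubted arrays (0.939) and without ambient ample midnight replicate 4 (0.977), with 0.00425 to 0.977 over single arrays left out. The plastid-encoded gene expression machinery lay lower in the N effect, ambient CO2, midnight (adjusted p = 0.0317, and adjusted p = 0.882 with an estimated correlation), and turned upward without both (0.879) and without the same array (0.879), with 0.000788 to 0.879 over single arrays left out.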

Other observations

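The 9 lists of this part, and so their tests, were chosen after array quality and counts had been seen, and 40 of 117 tests in the planned contrasts passed, 1 of them with an estimated correlation, and 37 of 81 in the averages, 0 of them with an estimated correlation. Genes of protein folding in the endoplasmic reticulum lay mostly above 0 at elevated CO2, with 11 and 10 of 13 above 0 at ample nitrogen at midday and midnight, and 11 and 13 at limiting nitrogen. In the same order the list gave adjusted p = 0.0126, 0.000575, 0.00135 and 0.000313, and with an estimated correlation adjusted p = 0.922, 0.375, 0.231 and 0.17. In the average over conditions 5 rose, BZIP60, a transcription factor of the unfolded protein response, by 0.72 (SE 0.13, adjusted p = 0.000802), ATERDJ3B by 0.69 (SE 0.16), CRT1b, a calreticulin, by 0.57 (SE 0.12), DER1 by 0.45 (SE 0.125) and OS9 by 0.26 (SE 0.08). Of 11 autophagy genes APG8A rose by 0.38 (SE 0.105) and ATG8D by 0.355 (SE 0.1), and 9 did not pass (list adjusted p = 0.0156, and adjusted p = 0.376 with an estimated correlation). All 10 nuclear-encoded plastid ribosomal genes lay below 0, and 7 fell, among them AT5G47190 by 0.40 (SE 0.1) and AT3G54210 by 0.31 (SE 0.08) (list adjusted p = 0.000179, and adjusted p = 0.376 with an estimated correlation). Of 7 tubulin genes TUB5 fell by 0.36 (SE 0.12), TUB7 by 0.29 (SE 0.09) and TUB6 by 0.25 (SE 0.075), and 4 did not pass (list adjusted p = 0.0406, and adjusted p = 0.376 with an estimated correlation).

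Under limiting nitrogen at elevated CO2, 108 of 109 cytosolic ribosomal genes lay below 0 at midday (median -0.475), of which 0 passed over all probe sets and 61 when adjusted over the list alone (limma). The list gave adjusted p = 8.19e-57, and adjusted p = 0.015 with an estimated correlation. At midnight 82 lay below 0 (median -0.08, adjusted p = 0.0375, and adjusted p = 0.8 with an estimated correlation). At ambient CO2 the genes went both ways at midday, with 60 below and 49 above 0 (median -0.01, adjusted p = 0.865), and at midnight 98 of 109 lay below 0 (adjusted p = 1.37e-10, and adjusted p = 0.736 with an estimated correlation).

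In the average CO2 effect, EXPA8, an expansin, fell by 0.71 (SE 0.17, adjusted p = 0.00448), ATSPS4F, a sucrose phosphate synthase, by 0.54 (SE 0.14, adjusted p = 0.00901), while SAG101 rose by 0.50 (SE 0.145, adjusted p = 0.0144) and BCAT4 by 0.53 (SE 0.15, adjusted p = 0.0148).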
